A study of Mus musculus with 12 samples.

How the data were processed

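The measurements are RNA-seq expression values of alveolar macrophages from mouse lungs, 4 libraries each of naive lungs and of lungs 2 h and 24 h after reperfusion in a transplant model. Per the labels' protocols, RNA was isolated with the PicoPure kit and polyadenylated RNA was sequenced with standard Illumina libraries. The authors deposited a table of RPKM values per Ensembl gene, with a column per library. Per the submitters' processing notes, bcl2fastq, TopHat2 and HTSeq were used and the build was mm10. Versions, the annotation, the definition of gene length and any filters are not given in the sources used here. The titles of the reperfusion libraries hold the word Allo, which the labels do not explain. Each library was put in its group by its time point label. Nothing says that the libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be technical.

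The table held 43430 genes, 42462 of them (97.8%) with a symbol in the reference annotation, and 24505 were above 0 in at least 1 library. Symbols, positions and gene types came from GENCODE annotation of the same assembly as mm10. RPKM values multiplied by gene length fell on whole multiples of a step in each library, which gave the library totals behind the values, 6112586 to 11997945 reads. Whole reads within 0.02 of a read were recovered for 11396 of 11419 tested genes (99.8%), and these reads made up 98.1 to 98.3% of each library total. The gene length implied by the authors' values equalled the exon union of the annotation in 14.2% of genes and exceeded it in 60.7%, with a median ratio of 1.3, so RPKM levels of different genes are not compared here. A gene of 1 kb with 3 reads had an RPKM of 0.25 to 0.491, depending on the library, which is the limit that a count of 0 allows. These limits cover counting error only. At most 21.4% of the values were identical between any 2 libraries.

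Genes with an RPKM of at least 1 in at least 4 of the 12 libraries were tested, 11419 in all. limma 3.58.1 in R 4.3.3 was fitted to log2(RPKM + 1) over all 12 libraries, which share an estimate of the spread, with a variance trend and two-sided moderated tests. p-values were adjusted by the Benjamini-Hochberg method over all genes tested, separately for each of the 3 comparisons, with a threshold of 0.05. Fold changes on the log2(RPKM + 1) scale understate the change of genes with low values, and folds given as ratios are ratios of mean RPKM. RPKM values are not counts, so this test is not a count model, and voom, which takes counts, was run on the recovered reads as another setting. The steps were tested on simulated data with 24 h against naive as the model. Of 67 genes changed 1.5-fold 50.7% were recovered, of 67 changed 2-fold 95.5%, and of 66 changed 4-fold 98.5%, among 11232 genes, with 10 false calls. The changed genes were drawn from those with a naive mean of at least 2 RPKM. The simulated spread was set by a formula and was equal in all groups. These rates therefore do not carry over to lower genes or to groups with a wider spread.

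The gene lists and the rule for named genes were fixed before the data were examined. There are 31 lists with 649 symbols, 645 of them in the table, covering pathways and the markers of alveolar macrophages and of other cell types. The 28 lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, again with a correlation estimated from the data, and with fry, adjusted over the lists. fry tests whether a list's genes move on balance one way and compares them with no other genes. Genes are named by a rule, which takes the 6 largest rises and 6 largest falls of each comparison among genes that passed, with a mean of at least 5 RPKM in the higher group and no overlap between the libraries, predicted and clone names left out (Gm with digits, symbols ending in Rik or -ps, and those starting with AC, AI, AA or BC and digits), and up to 3 members of each list with the smallest p. Genes chosen after their values were seen are said to be so. Some genes that the rule names are not reported here. A gene is called early and transient if it changed at 2 h and changed back at 24 h against 2 h, late if it changed at 24 h against both naive and 2 h in the same direction but not at 2 h, and maintained if it changed in the same direction at both times.

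The fits were repeated with 26 other settings, 23 planned and 3 chosen after seeing the data. Planned were pseudocounts of 0.1 and 0.5, no filter, a filter at 5 RPKM, median-ratio scaling, quantile normalisation, equal totals (TPM), no variance trend, library weights, the 2 compared groups alone, the replicate number as a block and each library left out in turn. Chosen after seeing the data were limma voom on the recovered reads, protein-coding genes only, and the fit without the naive and 24 h libraries numbered 4. Near-identical copies of genes were found with BLAST 2.17.0 on the annotated transcripts, at an identity of at least 90% over at least 50% of the copy. Other tools were Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.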

Results

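Alveolar macrophages, the resident phagocytes of the air spaces, were profiled by RNA sequencing of polyadenylated RNA in a murine lung transplant model. The 12 libraries fell into 3 groups of 4: naive lungs, lungs 2 h after reperfusion and lungs 24 h after reperfusion, reperfusion being the return of blood flow to the graft. All 12 are labelled as male mice of 14 weeks with the same Cx3cr1 reporter genotype on a B6 background. Library totals were read from the steps of the deposited RPKM values (reads per kilobase of gene model, scaled to the library total). They ranged from 6112586 to 8796071 reads in naive, from 7242824 to 10347265 at 2 h and from 9129420 to 11997945 at 24 h. Pearson's r between libraries of a group, taken across the 11419 tested genes, which are not independent replicates, was 0.968 to 0.987, against 0.909 to 0.96 between libraries of different groups. The first principal component held 45.9% of the variance and the second 22.1%.

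The first comparison asks what had changed in these cells 2 h after reperfusion. Chemokine and cytokine genes were among those that rose. Ccl3, a chemokine ligand that recruits leukocytes, went from 14.5 ± 4.92 RPKM (SD, n = 4) in naive to 87.9 ± 27.7 RPKM (SD, n = 4) at 2 h, a 6.05-fold rise (log2 fold change 2.51 ± 0.24, SE, adjusted p = 2.49e-05). All 4 libraries at 2 h lay above all 4 naive libraries. Ccl9 and Cxcl14, chemokines as well, rose 3.36-fold and 3.58-fold. Tnf rose 2.26-fold, Il1a 2.79-fold and Il1b 2.34-fold, with adjusted p of 0.000185, 0.000223 and 0.0145, all genes of inflammatory cytokines. In 2 h replicate 3 Il1b was 5.71 RPKM, within the naive range of 4.6 to 7.02 RPKM. Of 13 tested chemokine genes, 8 rose, 0 fell and 5 did not pass (9 rose adjusted over the list alone). The median log2 fold change was 0.61 (camera adjusted p = 0.00019, adjusted p = 0.213 with an estimated correlation). Of 9 tested cytokine genes, 5 rose, 0 fell and 4 did not pass (5 rose adjusted over the list alone). The median was 0.56 (camera adjusted p = 0.0103, adjusted p = 0.213 with an estimated correlation). Without 2 h replicate 3 the chemokine median was 1.03, and without 2 h replicate 1 the cytokine median was 0.33, both still called.

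Some immediate early genes rose too. Atf3, a stress-induced transcription factor, rose 3.99-fold to 39.8 ± 14.7 RPKM (SD, n = 4, adjusted p = 0.000542), Maff rose 3.08-fold and Ier3 rose 3.82-fold. Nr4a1, an immediate early nuclear receptor, was 10.6 ± 2.13 RPKM (SD, n = 4) in naive and 52.7 ± 43.5 RPKM (SD, n = 4) at 2 h (log2 fold change 1.79, adjusted p = 0.019), and without 2 h replicate 2 it did not pass (log2 fold change 1.53). Of 21 tested immediate early genes 6 rose, 1 fell and 14 did not pass (6 and 1 adjusted over the list alone). The median was 0.31 (camera adjusted p = 0.0475, adjusted p = 0.704 with an estimated correlation). This call was lost in 12 of 26 other fits, among them those without 2 h replicate 1 (median 0.15), 2 h replicate 2 (0.20), naive replicate 1 (0.30), naive replicate 3 (0.33), and 24 h replicate 1 or 4 (0.31 each). The other 6 were the pseudocount of 0.1, the filter at 5 RPKM, median-ratio scaling, quantile normalisation, the 2 groups alone and the replicate block, and fry did not call the list either. Without 2 h replicate 3 the median was 0.53 and the call was kept. Socs3, a feedback inhibitor of cytokine signalling, rose 10.8-fold on average (log2 fold change 2.73 ± 0.66, SE, adjusted p = 0.00775), with 42.2, 99.97, 88.1 and 7.73 RPKM in the 2 h libraries against 4.28 to 6.33 RPKM in naive. Nfkbia, the inhibitor that NF-kappaB itself induces, rose 2.67-fold (adjusted p = 0.000204). Of 17 tested NF-kappaB genes 5 rose, 2 fell and 10 did not pass (5 and 2 adjusted over the list alone, median 0.13, camera adjusted p = 0.0992). Tlr2, a receptor for bacterial lipoproteins, rose 1.88-fold (adjusted p = 6.72e-05), whereas of 21 pattern recognition genes 3 rose, 9 fell and 9 did not pass (3 and 9 adjusted over the list alone, camera adjusted p = 0.981).

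Genes of the NRF2 antioxidant response rose at 2 h. Srxn1, which repairs oxidised peroxiredoxin, rose 3.45-fold (adjusted p = 0.000118), Txnrd1 2.36-fold (adjusted p = 0.00035) and Fth1, the ferritin heavy chain, 1.47-fold (adjusted p = 0.000734, a call lost when no filter on low values was used). Of 18 tested members 10 rose, 1 fell and 7 did not pass (10 and 2 adjusted over the list alone). The median log2 fold change was 0.44 (camera adjusted p = 0.00362, adjusted p = 0.502 with an estimated correlation). Slc2a1, the main glucose transporter, rose 3.17-fold and Pgam1, a glycolytic enzyme, 1.81-fold. In the hypoxia and glycolysis list 7 of 22 rose, 1 fell and 14 did not pass (7 and 1 adjusted over the list alone, median 0.12, camera adjusted p = 0.00863, adjusted p = 0.502 with an estimated correlation). Spp1 rose 2.43-fold and the macrophage elastase Mmp12 went from 0.67 ± 0.0917 to 4.37 ± 1.79 RPKM (SD, n = 4 each). Of 15 matrix remodelling genes 7 rose, 2 fell and 6 did not pass (9 and 3 adjusted over the list alone, median 0.30, camera adjusted p = 0.0124, adjusted p = 0.213 with an estimated correlation). Of 31 lysosomal genes 10 rose, 3 fell and 18 did not pass (10 and 3 adjusted over the list alone, median 0.07, camera adjusted p = 0.0255, adjusted p = 0.502 with an estimated correlation). That call was lost without naive replicate 3 (median 0.05) and with quantile normalisation (0.02). Of 13 genes of the mitochondrial genome 4 rose, 0 fell and 9 did not pass (4 adjusted over the list alone, median 0.27, camera adjusted p = 0.0103, adjusted p = 0.502 with an estimated correlation). It was not called with quantile normalisation (median 0.10), nor was the matrix list with no filter (median 0.09).

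Among the genes with the largest changes by the rule for named genes, which leaves out symbols ending in -ps, Rarres1 rose 10.3-fold, from 1.77 ± 0.502 to 18.2 ± 1.36 RPKM (SD, n = 4 each, adjusted p = 5.84e-07). Tpm3-rs7, a near-identical copy of the tropomyosin gene Tpm3, went from 0.375 ± 0.134 to 26.4 ± 3.05 RPKM (SD, n = 4 each), and Pianp from 0.0959 ± 0.0262 to 5.53 ± 0.638 RPKM (SD, n = 4 each). Mir23b and Snord49b also belonged to the 6 largest rises by that rule, but both are very short genes, with 5 to 9 and 2 to 9 recovered reads per 2 h library against 0 and 0 to 1 in naive. Tpm3-rs7, Pianp and Mir23b belong to the 38 genes near 0 in naive that are described below. Their rises, like every other change at 2 h against naive, cannot be told apart from a difference between the groups other than time. Clec2d, a C-type lectin gene, fell by 1.86 on the log2 scale. It went from 53.8 ± 3.14 to 14.9 ± 5.46 RPKM (SD, n = 4 each, adjusted p = 8.02e-05). Tppp (log2 fold change -1.77), Fam111a (-1.63), Fpr1, a receptor for formylated peptides (-1.56), Rnase6 (-1.54) and Calcrl (-1.35) were the other largest falls by that rule. Klf9 and Per1, which glucocorticoids induce, rose 4.67-fold and 3.45-fold (adjusted p = 6.16e-05 and 0.000323), and Mt2, a metallothionein, rose 7.31-fold on average with 107 to 803 RPKM across the 2 h libraries. Per1 was chosen after its values were seen. No list of genes that glucocorticoids induce was among those tested, so these rises are not assigned to a cause here.

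Cell cycle genes fell at 2 h. Mcm6 and Mcm7, subunits of the replicative helicase, fell with log2 fold changes of -0.72 and -0.45 (adjusted p = 0.000186 and 0.000274). Of 31 members 0 rose, 23 fell and 8 did not pass (26 fell adjusted over the list alone). The median log2 fold change was -0.39 (camera adjusted p = 2.52e-07, adjusted p = 0.429 with an estimated correlation). Krt19, Pparg and Chil3 of the alveolar macrophage identity list fell (log2 fold changes -0.85, -0.51 and -0.66), Chil3 not passing when no filter was used. The list of 25 had 5 members higher, 7 lower and 13 that did not pass (5 and 8 adjusted over the list alone, camera adjusted p = 0.839). Pparg is the transcription factor on which alveolar macrophage differentiation depends. Hspa8, a constitutive heat shock protein, fell by 1.25 on the log2 scale (adjusted p = 0.0117), and of 13 heat shock genes 0 rose, 3 fell and 10 did not pass (3 fell adjusted over the list alone, median -0.46, camera adjusted p = 0.268).

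Lists without a camera call at 2 h were these, counted as risen, fallen and not passed. Type I interferon genes gave 0, 4 and 7, interferon-gamma genes 0, 5 and 5, MHC class II genes 1, 3 and 7, the unfolded protein response 2, 2 and 13, and lipid handling 2, 7 and 16. MHC class I genes gave 2, 3 and 12, with H2-Q4 2.22-fold higher (adjusted p = 2.77e-06), a gene with close paralogs whose reads cannot be told apart with certainty. Sterol synthesis gave 1, 8 and 13, with Hmgcs1 and Sqle lower by log2 fold changes of -0.57 and -0.39. Oxidative phosphorylation gave 2, 1 and 30, efferocytosis and resolution 3, 2 and 6, and ribosomal proteins 1, 2 and 30, where Rplp0 fell by 0.35 on the log2 scale. Hspa8 and Rplp0 each have near-identical copies that gained reads at 2 h, so the size of their falls is uncertain.

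More markers of other cell types fell than rose at 2 h, and 17 of 31 did not pass. Lymphocyte markers fell in 5 of 5 tested genes (5 adjusted over the list alone, median -0.83, camera adjusted p = 0.0191, adjusted p = 0.481 with an estimated correlation), among them Nkg7 (log2 fold change -0.83) and Cd79a (-0.76). With a pseudocount of 0.1 the list was not called (median -1.23). C1qa, a complement gene of interstitial macrophages, fell by 1.58 on the log2 scale to 0.483 ± 0.156 RPKM (SD, n = 4). It belongs to a list with 0 higher, 3 lower and 2 not passed (camera adjusted p = 0.0689). Monocyte markers gave 0 higher, 3 lower and 3 not passed, neutrophil markers 0, 1 and 5, epithelial markers 1, 0 and 4, dendritic cell markers 0, 1 and 2 and the endothelial and stromal list 0, 0 and 1, while 0 of the red cell and platelet markers were tested. Of the 31 tested markers of the 8 lists together, 1 was higher and 13 were lower at 2 h. The 4 libraries at 2 h also carried 38 genes that were near 0 in naive, with a mean of at least 2 RPKM at 2 h, at most 5% of it in naive and no overlap (chance places the 2 h libraries wholly above naive in 1.43% of orders). These genes, on 16 chromosomes and including 23 pseudogenes, were identified after the values were seen. The reverse set, on in naive and near 0 at 2 h, held 0 genes. H2-Ea-ps (chromosome 17, 34341959 to 34344645, mm10), which encodes the MHC class II E-alpha chain and is annotated as a polymorphic pseudogene in this B6 reference, had 23.1 ± 3.19 RPKM (SD, n = 4) at 2 h, 0.046 ± 0.0919 in naive and 3.37 ± 2.06 at 24 h. Ifi202b (chromosome 1, 173962568 to 173982744), an interferon-inducible gene, was listed at 0 in all 4 naive libraries and had 2.0 ± 0.232 RPKM (SD, n = 4) at 2 h. Gm8730, a processed pseudogene near-identical to Rplp0, went from 0.348 ± 0.486 to 47.5 ± 4.51 RPKM (SD, n = 4 each). Of the 38 genes, 27 have an expressed parent of at least 90% identity, so their reads cannot be told apart from the parent's with certainty. Named parents of these copies are Eno1, Hspa8 and Rplp0. Other named genes with known paralogs or processed pseudogenes, such as Pgam1, Fth1, Ftl1, Chil3, Ear2 and Hist1h2bc, may share reads too, and their copies were not searched for here. H2-Ea-ps, Ifi202b and Gm8730 were chosen after their values were seen.

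In all, 4189 of 11419 tested genes differed between 2 h and naive by limma at an adjusted p under 0.05, 1675 higher and 2514 lower, and 2039 higher and 2052 lower with median-ratio scaling. With an absolute log2 fold change of at least 1 the counts were 223 higher and 69 lower, and they depended on the treatment of low values. There were 306 and 240 with a pseudocount of 0.1, 268 and 129 with 0.5, 307 and 300 with voom on recovered reads, 124 and 41 with the filter at 5 RPKM, and 126 and 46 among protein-coding genes only. Camera called 10 of 28 lists with its preset correlation and 0 with an estimated correlation (3 had an unadjusted p under 0.05), while fry called 16. All 4 libraries at 2 h carry the 38 genes near 0 in naive, so the counts and lists of this comparison cannot separate time from any other difference between the 2 groups.

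**Figure D1:**
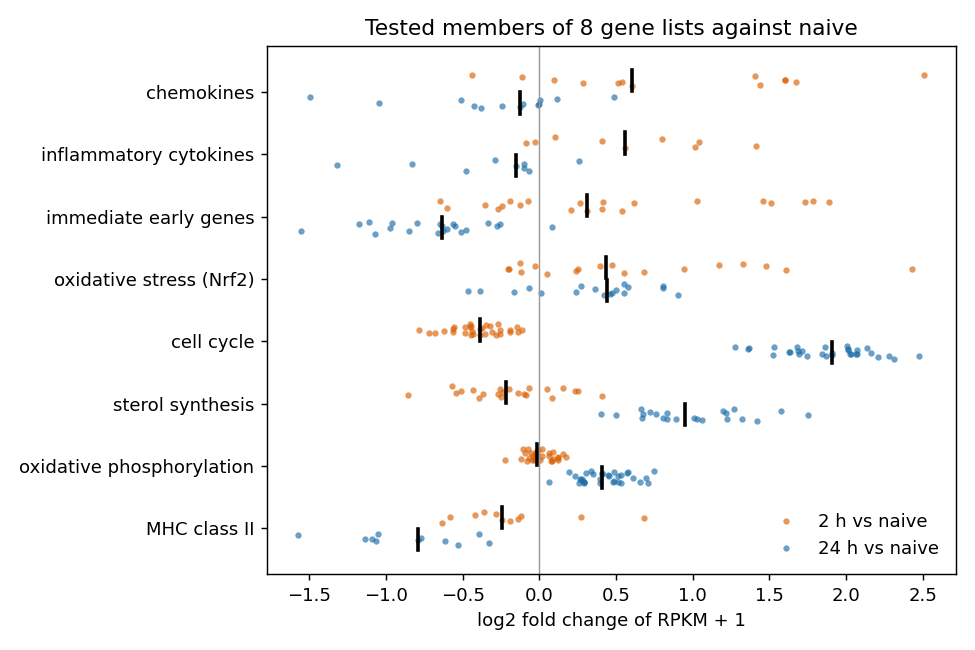
Each point is a tested gene of a list fixed before the data were examined, placed by its log2 fold change of RPKM + 1 against naive at 2 h (orange) and 24 h (blue), with black bars at the list medians. The cell cycle list had a median of -0.39 at 2 h and 1.91 at 24 h.

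The second comparison sets 24 h after reperfusion against naive. Cell cycle genes rose. Pclaf, a PCNA-binding factor, went from 4.99 ± 0.151 to 37.9 ± 2.97 RPKM (SD, n = 4 each), 7.6-fold higher (log2 fold change 2.70 ± 0.07, SE, adjusted p = 9.77e-10). Rrm2 and Rrm1, subunits of ribonucleotide reductase, rose 5.98-fold and 4.67-fold, and Mcm5 rose 5.37-fold, Shcbp1 6.46-fold, Cdkn3 7.02-fold and the mitotic kinase Plk1 5.46-fold. Esco2 and the spindle motor Kif11 rose 5.35-fold and 4.41-fold. All 31 tested genes of the cell cycle list, which does not hold Pclaf, Shcbp1, Cdkn3 or Esco2, rose (31 adjusted over the list alone). The median log2 fold change was 1.91 (camera adjusted p = 4.14e-26, adjusted p = 0.175 with an estimated correlation).

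Sterol synthesis genes, which SREBP2 controls, rose in 22 of 22 (22 adjusted over the list alone). The median log2 fold change was 0.95 (camera adjusted p = 2.67e-12, adjusted p = 0.175 with an estimated correlation). Sqle, squalene epoxidase, rose 3.11-fold, Hmgcs1 2.32-fold and Hsd17b7 3.07-fold (adjusted p = 4.28e-08, 6.91e-08 and 1.65e-07). Abca1 and Abcg1, which export cholesterol, fell (log2 fold changes -1.67 and -1.12, adjusted p = 2.22e-06 and 9.25e-07). The lipid handling list of 25 gave 5 higher, 8 lower and 12 not passed (5 and 8 adjusted over the list alone, camera adjusted p = 0.361). Nuclear-encoded oxidative phosphorylation genes rose in 30 of 33, 0 fell and 3 did not pass (32 adjusted over the list alone). Their median was 0.41 (camera adjusted p = 1.46e-11, adjusted p = 0.175 with an estimated correlation). The ATP synthase genes Atp5b and Atp5a1 rose by log2 fold changes of 0.49 and 0.53. Eno1, Pgk1 and Pgam1, glycolytic enzymes, rose 2.65-fold, 2.08-fold and 2.83-fold. The hypoxia and glycolysis list had 13 higher, 1 lower and 8 not passed (14 and 1 adjusted over the list alone, median 0.48, camera adjusted p = 0.00161, adjusted p = 0.338 with an estimated correlation). Fth1, Ftl1 and Txn1 of the NRF2 list rose 1.76-fold, 1.9-fold and 1.47-fold. In that list 10 members rose, 1 fell and 7 did not pass (11 and 2 adjusted over the list alone, median 0.44, camera adjusted p = 0.0232, adjusted p = 0.542 with an estimated correlation), a call lost with the filter at 5 RPKM (median 0.44).

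MHC class II genes, which present antigen to helper T cells, fell in 11 of 11 (11 adjusted over the list alone). The median log2 fold change was -0.79 (camera adjusted p = 2.66e-05, adjusted p = 0.193 with an estimated correlation). H2-DMa, which loads peptides onto class II, went from 122 ± 3.91 to 40.5 ± 5.68 RPKM (SD, n = 4 each, adjusted p = 8.22e-08). H2-DMb2 fell by 1.07 and Cd74, the invariant chain, fell by 1.09 on the log2 scale. The B cell marker Cd79a fell too, from 3.23 ± 0.697 to 0.449 ± 0.294 RPKM (SD, n = 4 each), as did 5 of 5 lymphocyte and 4 of 5 interstitial macrophage markers, so the class II fall is not assigned to a cell type here. Of 17 MHC class I genes 2 rose, 9 fell and 6 did not pass (2 and 9 adjusted over the list alone, median -0.31, camera adjusted p = 0.0169, adjusted p = 0.272 with an estimated correlation). B2m and H2-T23 fell (log2 fold changes -0.54 and -0.71). Of 10 interferon-gamma genes 0 rose, 4 fell and 6 did not pass (4 fell adjusted over the list alone, median -0.25, camera adjusted p = 0.0167, adjusted p = 0.201 with an estimated correlation). The type I interferon list gave 1 higher, 3 lower and 7 not passed (0 and 3 adjusted over the list alone, camera adjusted p = 0.532).

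Some immediate early, NF-kappaB and pattern recognition genes fell below naive at 24 h. Of 21 immediate early genes 0 rose, 9 fell and 12 did not pass (9 fell adjusted over the list alone, median -0.63, camera adjusted p = 0.000673, adjusted p = 0.338 with an estimated correlation). Jund and Ier5 fell (log2 fold changes -1.11 and -1.07). NF-kappaB genes gave 1 higher, 9 lower and 7 not passed (2 and 9 adjusted over the list alone, median -0.34, camera adjusted p = 0.00712, adjusted p = 0.175 with an estimated correlation), and Tnfaip2 (-0.86) and Nfkb2 (-0.71) fell. Pattern recognition genes gave 2 higher, 12 lower and 7 not passed (2 and 13 adjusted over the list alone, median -0.31, camera adjusted p = 0.00413, adjusted p = 0.201 with an estimated correlation), and Tlr7 (-0.86) and Tlr2 (-0.65) fell. Il1b fell by 1.32 on the log2 scale (adjusted p = 0.00233) and Cxcl3 fell to 0.832 ± 0.0776 RPKM from 4.2 ± 0.703 (SD, n = 4 each, adjusted p = 2.36e-07). In 24 h replicate 4 Il1b was 2.71 RPKM, against 1.26 to 1.34 in the other 3. The cytokine list gave 0 higher, 3 lower and 6 not passed (camera adjusted p = 0.154) and the chemokine list 1, 1 and 11 (camera adjusted p = 0.235).

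Among alveolar macrophage identity genes 4 rose, 15 fell and 6 did not pass (4 and 15 adjusted over the list alone). The median was -0.25 (camera adjusted p = 0.00872, adjusted p = 0.272 with an estimated correlation). Krt19, Itgax, which encodes an integrin chain, and Pparg fell (log2 fold changes -1.12, -0.84 and -0.30). Marco, a scavenger receptor, rose 4.19-fold, from 94.9 ± 10.6 to 398 ± 25.8 RPKM (SD, n = 4 each, adjusted p = 3.56e-06), and Chil3 was 7780 ± 295 and 7802 ± 619 RPKM (adjusted p = 0.991), but fell with quantile normalisation (log2 fold change -0.46). Ear2 fell by 0.93 on the log2 scale, Car4 rose 2.17-fold and Lrg1 5.34-fold (adjusted p = 0.00052, 0.000242 and 2.34e-05). Ear2, Car4 and Lrg1 were chosen after their values were seen. The largest falls by the rule for named genes were those of Tppp (log2 fold change -2.35), Tcim (-2.25), Slpi, a secreted protease inhibitor (-2.23), Tppp3 (-2.14), Hist1h2bc (-1.99) and Mir7678 (-2.57). Mir7678 lies within Slpi and had 0 to 4 recovered reads per library at 24 h against 7 to 22 in naive. The lysosomal list had 16 higher, 6 lower and 9 not passed (16 and 7 adjusted over the list alone, camera adjusted p = 0.303).

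Heat shock genes gave 3 higher, 0 lower and 10 not passed, the unfolded protein response 1, 2 and 14, efferocytosis and resolution 2, 5 and 4, matrix remodelling 3, 5 and 7, the mitochondrial genome 4, 0 and 9 and ribosomal proteins 18, 3 and 12, without a camera call. Markers of other cells went both ways at 24 h, 6 of 31 higher and 17 lower. Lymphocyte markers fell in 5 of 5 (5 adjusted over the list alone, median -1.34, camera adjusted p = 0.00172, adjusted p = 0.247 with an estimated correlation). Interstitial macrophage markers gave 1 higher and 4 lower, and C1qa fell by 1.52 on the log2 scale (list median -0.97, 1 and 4 adjusted over the list alone, camera adjusted p = 0.049, adjusted p = 0.247 with an estimated correlation). That call was lost in 15 of 25 other fits, among them those without naive replicate 3 (median -0.94), naive replicate 4 (-0.95), 24 h replicate 1 (-0.87) or any of the 4 libraries at 2 h (-0.97 each). It was also lost with pseudocounts of 0.1 (-1.91) and 0.5 (-1.36), voom (-2.11), quantile normalisation, equal totals, library weights, the 2 groups alone and without both libraries numbered 4. Neutrophil markers gave 3 higher, 1 lower and 2 not passed, with S100a8 2.93-fold higher and Lcn2 at 66 to 124 recovered reads per library against 0 to 4 in naive. Monocyte markers gave 1 higher (Ms4a6c, 2.99-fold), 4 lower and 1 not passed, epithelial markers 0, 1 and 4, the fall being that of Epcam (log2 fold change -1.75), dendritic cell markers 1, 1 and 1 and the endothelial and stromal list 0, 1 and 0.

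In all, 5241 genes differed between 24 h and naive by limma, 2887 higher and 2354 lower. With quantile normalisation 2557 were higher and 2738 lower, and with equal totals 2630 and 2605, so which direction held more genes depended on the scaling. With an absolute log2 fold change of at least 1 there were 396 and 163, which were 555 and 277 with a pseudocount of 0.1 and 563 and 326 with voom. Camera called 14 of 28 lists with its preset correlation and 0 with an estimated correlation (6 had an unadjusted p under 0.05), while fry called 23. In the set of 38 genes near 0 in naive and present at 2 h, 24 h replicate 4 was the highest of the 24 h libraries for 32. Against naive, 2 genes were on at 24 h by the same rule. H2-Ea-ps, of the set of 38, was 1 of them, with 1.7, 1.48, 5.2 and 5.11 RPKM in 24 h replicates 1 to 4 (log2 fold change 1.94, limma adjusted p = 0.000143). The comparison of 24 h with naive is thus not free of the genes of this set.

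**Figure D2:**
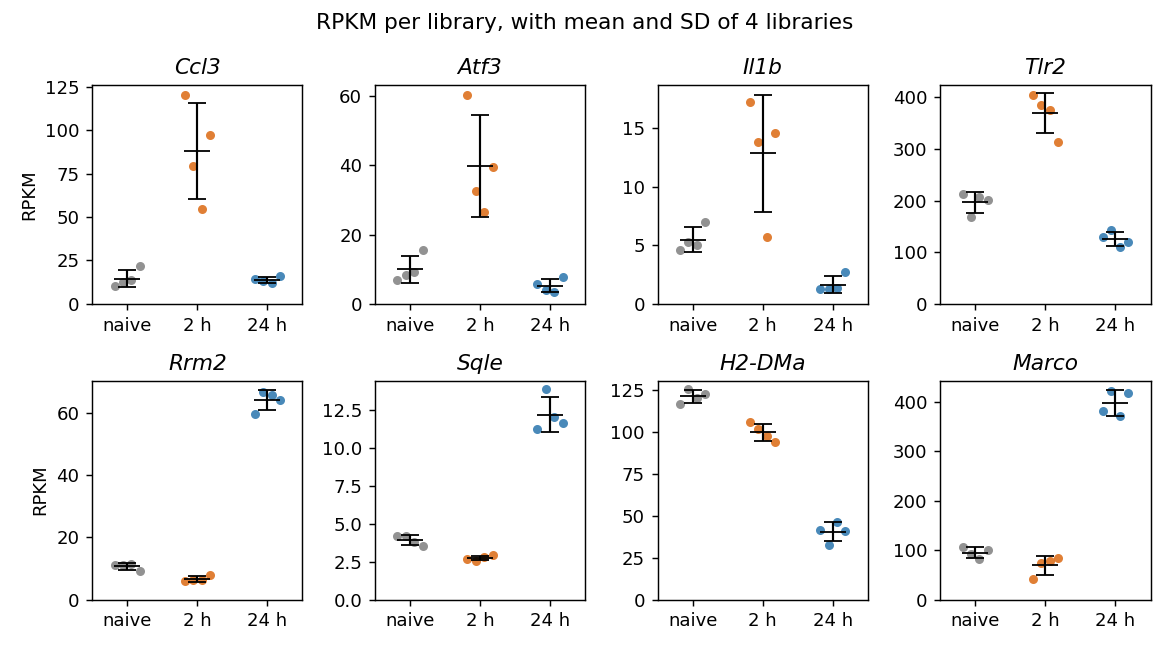
RPKM of 8 genes in each library (points) of naive, 2 h and 24 h, with the mean (horizontal bar) and SD (error bars) of 4 libraries, on axes that start at 0. Ccl3 and Tlr2 had their highest means at 2 h (87.9 and 369 RPKM), and Rrm2 and Marco at 24 h (64.0 and 398 RPKM).

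The third comparison, 24 h against 2 h, tests the difference between the times directly. Cell cycle genes rose in 31 of 31 (31 adjusted over the list alone, median 2.26, camera adjusted p = 2.62e-23, adjusted p = 0.0855 with an estimated correlation). The largest rises by the rule for named genes were those of Pclaf (12.7-fold), Rrm2 (9.65-fold), Cdkn3 (9.96-fold), Esco2 (11.5-fold), Kif11 (8.29-fold) and Shcbp1 (8.69-fold). Sterol synthesis rose in 22 of 22 (22 adjusted over the list alone, median 1.11, camera adjusted p = 9.96e-11, adjusted p = 0.135 with an estimated correlation). Oxidative phosphorylation rose in 32 of 33 with 1 not passed (32 adjusted over the list alone, median 0.43, camera adjusted p = 9.97e-09, adjusted p = 0.135 with an estimated correlation). Marco rose 5.73-fold (adjusted p = 4.06e-07).

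Inflammatory genes fell from 2 h to 24 h. Chemokines fell in 11 of 13 with 2 not passed (11 adjusted over the list alone, median -1.38, camera adjusted p = 1.11e-05, adjusted p = 0.0855 with an estimated correlation). Cytokine genes fell in 7 of 9 with 2 not passed (7 adjusted over the list alone, median -0.66, camera adjusted p = 0.00173, adjusted p = 0.0855 with an estimated correlation). Immediate early genes fell in 15 of 21 with 6 not passed (15 adjusted over the list alone, median -1.02, camera adjusted p = 7.1e-06, adjusted p = 0.271 with an estimated correlation). Ccl3, Il1b, Tnf and Tlr2 fell with log2 fold changes of -2.52, -2.33, -1.33 and -1.55. The largest falls by the same rule were those of Tpm3-rs7 (-3.87), Mt2 (-2.82), Mir23b (-2.77, on 0 to 1 recovered reads per library at 24 h), Nr4a1 (-2.75), Atf3 (-2.69) and Klf9 (-2.65). Tpm3-rs7 and Mir23b belong to the 38 genes near 0 in naive and present in every 2 h library. NF-kappaB genes gave 1 higher, 11 lower and 5 not passed (1 and 11 adjusted over the list alone, median -0.52, camera adjusted p = 0.000284, adjusted p = 0.0855 with an estimated correlation). Matrix remodelling genes gave 3, 10 and 2 (3 and 10 adjusted over the list alone, median -0.60, camera adjusted p = 0.00432, adjusted p = 0.0855 with an estimated correlation).

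MHC class II genes fell in 9 of 11 with 2 not passed (9 adjusted over the list alone, median -0.72, camera adjusted p = 0.000749, adjusted p = 0.234 with an estimated correlation). MHC class I genes gave 3 higher, 9 lower and 5 not passed (3 and 9 adjusted over the list alone, median -0.28, camera adjusted p = 0.0201, adjusted p = 0.271 with an estimated correlation). Pattern recognition genes gave 3, 10 and 8 (3 and 10 adjusted over the list alone, median -0.18, camera adjusted p = 0.0204, adjusted p = 0.245 with an estimated correlation), with a median of -0.12 without 24 h replicate 2. Alveolar macrophage identity genes gave 7, 13 and 5 (7 and 14 adjusted over the list alone, median -0.27, camera adjusted p = 0.0217, adjusted p = 0.325 with an estimated correlation), a call lost without 2 h replicate 3 (median -0.24) and with quantile normalisation (-0.26). Epithelial markers gave 0, 3 and 2 (3 adjusted over the list alone, median -0.36, camera adjusted p = 0.0438, adjusted p = 0.148 with an estimated correlation). That call was lost in 8 of 25 other fits, among them those without 2 h replicate 3 (median -0.36), 24 h replicate 3 (-0.43) or 24 h replicate 4 (-0.42), and kept with a median of -0.59 without 24 h replicate 2. It was also lost with no filter (-0.08), median-ratio scaling, quantile normalisation, the replicate block and without both libraries numbered 4. The hypoxia and glycolysis list gave 11, 4 and 7, NRF2 genes 8, 7 and 3, lysosomal genes 8, 8 and 15, lipid handling 10, 10 and 5, heat shock 5, 0 and 8. Type I interferon genes gave 4, 1 and 6, interferon-gamma 1, 2 and 7, the unfolded protein response 4, 3 and 10, efferocytosis and resolution 2, 6 and 3, ribosomal proteins 15, 2 and 16 and the mitochondrial genome 0, 1 and 12, without a camera call. Lymphocyte markers gave 0, 2 and 3, monocyte markers 2, 2 and 2, neutrophil markers 3, 2 and 1, interstitial macrophage markers 0, 0 and 5, dendritic cell markers 1, 0 and 2 and the endothelial and stromal list 0, 1 and 0.

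In all, 5992 genes differed between 24 h and 2 h by limma, 3534 higher and 2458 lower (3033 and 2978 with quantile normalisation, 3172 and 2819 with median-ratio scaling). With an absolute log2 fold change of at least 1 there were 492 and 320, which were 715 and 507 with a pseudocount of 0.1, 750 and 543 with voom, 337 and 201 with the filter at 5 RPKM, and 448 and 205 among protein-coding genes only. Like the first comparison, this one cannot separate time from any other difference between the 2 h libraries and the rest. Camera called 13 of 28 lists with its preset correlation and 0 with an estimated correlation (8 had an unadjusted p under 0.05), while fry called 19. The median, mean and test of a list differed in sign for NRF2 genes (median 0.13, mean -0.28, camera down), the unfolded protein response (0.16, 0.09, down), interstitial macrophage markers (0.06, 0.07, down), lysosomal genes (0.01, 0.0, down) and monocyte markers (0.07, 0.18, down) at 24 h against 2 h. They also differed for type I interferon genes at 24 h against naive (0.06, -0.01, down) and, at 2 h against naive, for MHC class I genes (-0.03, 0.03, up), pattern recognition genes (-0.04, 0.01, up), lipid handling (-0.01, 0.02, up), neutrophil markers (0.07, -0.07, up), oxidative phosphorylation (-0.02, 0.0, up) and ribosomal proteins (0.0, -0.02, up). None of these was a camera call. For heat shock genes at 24 h against naive the median of -0.11 and camera pointed down and fry up. Fry also pointed the other way from camera for pattern recognition, lipid handling, oxidative phosphorylation, ribosomal protein and neutrophil genes at 2 h against naive, and for NRF2, lysosomal, monocyte and interstitial macrophage genes at 24 h against 2 h.

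By the order of the changes, 1057 genes were early and transient rises and 1428 were early and transient falls. The rises were higher at 2 h than in naive and lower again at 24 h than at 2 h. Any difference confined to the 2 h libraries would also place genes in these classes. Tpm3-rs7, Pianp and Gm8730, of the 38 genes near 0 in naive, were among the early and transient rises. Every class uses the 2 h libraries, so the class counts cannot separate time from any other difference between these libraries and the rest. Late rises numbered 1599 and late falls 907, and 529 genes were higher and 901 lower than naive at both times. The classes overlap. Of the genes called at both times against naive, 197 were higher at 2 h and lower at 24 h (126 without naive replicate 3), and 511 lower at 2 h and higher at 24 h. Since both times share the naive libraries, these overlaps were set beside those of independent lists of the same sizes, 423.5 genes for higher at both times, 518.3 for lower at both, 345.3 for higher then lower and 635.6 for lower then higher. With the naive libraries split 2 and 2, 247 to 276 genes were higher and 439 to 477 lower at both times over the 6 splits, beside 228.3 to 244.4 and 231.3 to 261 for independent lists. The log2 fold changes at both times had a covariance of 0.0372 across genes, against 0.0136 on average in 100 simulations of unchanged groups, a difference of 0.0236, and their correlation was 0.186 against 0.5011 in the simulations.

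**Figure D3:**
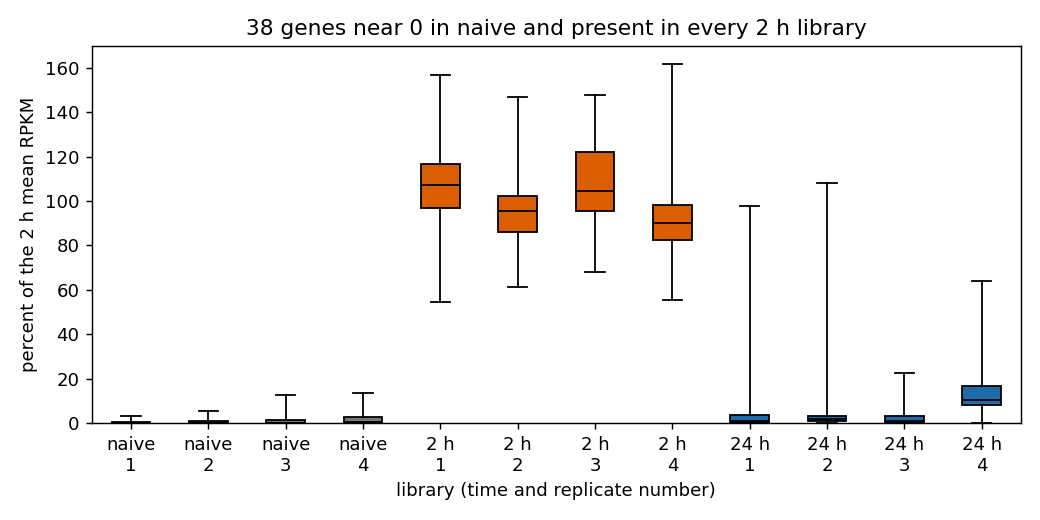
Box plots of 38 genes per library, each value given as the percent of that gene's mean RPKM at 2 h, with boxes at the quartiles, a line at the median and whiskers to the lowest and highest gene. The median was 0 to 0.33% in naive, 90.3 to 107% at 2 h and 1.0 to 2.07% in 24 h replicates 1 to 3, and 10.4% in 24 h replicate 4.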

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

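The tests of the 3 patterns and of the groupings were chosen after the results were seen, except the percent of the 2 h excess in 24 h replicate 4, whose limits were set before its value was known, and the scalings, single left-out libraries and comparisons used here were planned, but not the fit without both libraries numbered 4.

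The first pattern is the 38 genes near 0 in naive and present in every 2 h library, at a median of 90.3 to 107% of the 2 h mean, and of 10.4% in 24 h replicate 4. RNA of the cell types with at least 3 tested markers is argued against, since at most 20% of the markers of any such type were higher at 2 h (1 of 5 epithelial markers), and other cell types stay open. A strain variant could move reads from a parent gene to its near-identical copy, which stays open. The median parent change divided by the copy's gain was -1.33 over 27 pairs (quartiles -7.69 and 0.03). It was -0.41 over the 5 pairs with a gain of at least 10% of the parent (quartiles -0.56 and 0.01), where Gm10260 and Gm26619 share the parent Rps18. The use of quartiles was chosen after the pair values were seen. In the other pairs the gain was under 10% of the parent, so the ratio mostly shows the parent's own change and cannot decide. Genes without such a parent, among them H2-Ea-ps and Ifi202b, were not covered. RNA like that of the 2 h libraries in 24 h replicate 4 stays open, because the median percent of the 2 h excess found there over 147 other genes was 4.91, under the limit of 5 set in advance, while its upper quartile of 13.03 was above that limit (other 24 h libraries -1.74 to -2.94). Reperfusion and the time after it, the differences the design names, were not tested. They cannot be told apart from each other or from any other difference between the 2 h libraries and naive. H2-Ea-ps, annotated as a polymorphic pseudogene in this B6 reference, is among the 38 genes.

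The second pattern is the rise of the cell cycle list at 24 h. A difference in depth is argued against, since the lowest median log2 fold change over 20 thinnings of every library to 6112586 reads was 1.87. Scaling is argued against by the lowest median of 1.86 over 3 scalings. RNA of another cell type stays open, since 50% of the neutrophil markers (3 of 6) were higher at 24 h. That is too many to argue against it and not all that such cells would bring. In the other types with at least 3 tested markers, 0 to 33% were higher. Marker counts do not show whether cells of a type carry cell cycle RNA, so they cannot decide the source of the rise. Reperfusion in the transplant model, or the time after it, may be the source. The comparison with naive lungs, which have no reperfusion time, does not separate these. This hypothesis was found and tested on the same data.

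The third pattern is the rise of chemokine genes and of some immediate early genes at 2 h. Of 21 immediate early genes 6 rose, 1 fell and 14 did not pass, and the camera call of that list was lost in 12 of 26 other fits. Handling stress of the kind that raises heat shock genes was tested with the heat shock list, which did not rise (median log2 fold change -0.46). Of its 13 tested genes 0 rose, 3 fell and 10 did not pass, and camera did not call it (adjusted p = 0.268). Its members moved together (estimated correlation 0.838), so this list, which was not called, cannot decide. Such stress stays open, and other handling effects could remain too. A strain difference between the 2 h libraries and the others cannot be told apart from time. This holds here and for any gene, count or list of the comparisons with 2 h libraries. The reason is that 4 of the 4 libraries at 2 h carry the 38 genes, which no test ties to a strain, and none is without them. The labelled B6 background is the same for every library, so the labels do not account for the difference in these genes. Reperfusion and the time after it stay open as well.

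Splits of the 8 libraries of each comparison 4 and 4 cannot exclude chance differences between animals, since nothing says the libraries came from separate ones. Every split but the real one puts libraries of both groups on each side, so a low count there follows from any difference between the groups. Of the 35 splits, only the real one gave as many genes in each of the 3 comparisons. It gave 4189 genes at 2 h against naive, with 2 the highest of the other splits. For 24 h against naive it gave 5241, with 2 the highest other, and for 24 h against 2 h 5992, with 1 the highest other.

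Of 289 sets of 4 libraries, 20 had a library far from the other 3, where chance gives about 1 in 20. In 24 h replicate 4, Mir23b was 1.13 RPKM against 0 in the others, Pianp 0.475 against 0.0565 to 0.1, Il1b 2.71 against 1.26 to 1.34, Mmp12 0.97 against 0.0852 to 0.211, Gm8730 4.08 against 0.488 to 0.858 and Shcbp1 24.0 against 27.2 to 27.4. In naive replicate 4, Rrm2 was 9.14 RPKM against 11.1 to 11.3, Txn1 382 against 331 to 338, Ear2 2011 against 1741 to 1757, and the top 10 genes held 17% of the RPKM against 15.7 to 15.9%. In other naive libraries, Mir7678 was 39.1 RPKM in replicate 2 against 15.1 to 16.1, H2-Ea-ps 0.184 in replicate 2 against 0, H2-DMb2 6.72 in replicate 3 against 5.2 to 5.37 and Esco2 2.95 in replicate 1 against 2.51 to 2.58. At 2 h, replicate 4 had 8.05 RPKM of Rrm2 against 6.1 to 6.2, 5.47 of Kif11 against 3.65 to 3.77 and 12.7 of Nfkb2 against 14.1 to 14.3, and replicate 3 had 344 of Txn1 against 308 to 312. At 24 h, Tnfaip2 was 34.9 RPKM in replicate 1 against 29.0 to 29.8 and Lcn2 2.06 in replicate 2 against 1.3 to 1.38.

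Listed here are genes and lists that changed in opposite directions at 2 h and 24 h against naive, with the difference between the times passing its own test (24 h against 2 h). Differences in size alone are given by that comparison and not repeated. Higher at 2 h and lower at 24 h were Il1b (log2 fold changes 1.01 and -1.32), Atf3 (1.89 and -0.80), Tlr2 (0.90 and -0.65), Nfkb2 (0.36 and -0.71) and Nr1d1, a circadian repressor chosen after its values were seen (0.73 and -0.53). The 24 h call of Atf3 was lost without naive replicate 2 (-0.85), 3 (-0.82) or 4 (-0.58) and without 24 h replicate 1 (-0.85), 2 (-0.71) or 3 (-0.66), and with no filter. That of Nr1d1 was lost without naive replicate 4 (-0.51) and without 24 h replicate 2 (-0.44) or 4 (-0.47), without both libraries numbered 4 (-0.45) and with no filter, and the 2 h call of Nfkb2 without both libraries numbered 4 of naive and 24 h (0.33). Lower at 2 h and higher at 24 h were Mcm6 (-0.72 and 1.91), Mcm7 (-0.45 and 1.68), Pclaf (-0.59 and 2.70), Rrm2 (-0.62 and 2.48), Mcm5 (-0.45 and 2.31), Rrm1 (-0.45 and 2.16), Esco2 (-0.74 and 2.06), Kif11 (-0.78 and 2.01), Sqle (-0.39 and 1.42), Hmgcs1 (-0.57 and 1.2) and Ms4a6c (-0.61 and 1.46). The immediate early list had medians of 0.31 and -0.63 (adjusted p = 0.704 and 0.338 with an estimated correlation), and its 2 h call was lost in 12 of 26 other fits. The cell cycle list had medians of -0.39 and 1.91 (adjusted p = 0.429 and 0.175 with an estimated correlation). For 24 h against 2 h these were 0.271 for the immediate early list and 0.0855 for the cell cycle list.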

How the results depend on the processing

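Voom on recovered reads, protein-coding genes only and the fit without both libraries numbered 4 (naive and 24 h) were chosen after seeing the data. Across 26 other settings of the fit, every count of genes changed at an adjusted p under 0.05 stayed within 1.5 times its value, except with the filter at 5 RPKM, which tests 6467 genes in place of 11419 and gave 1544 lower at 2 h against naive, and 2307 higher and 1616 lower at 24 h against 2 h. An absolute log2 fold change of at least 1 left 223 higher and 69 lower at 2 h, 396 and 163 at 24 h, and 492 and 320 at 24 h against 2 h. These counts were 306 and 240, 555 and 277, and 715 and 507 with a pseudocount of 0.1, and 307 and 300, 563 and 326, and 750 and 543 with voom. With a pseudocount of 0.5, 129 were lower at 2 h. The filter at 5 RPKM gave 124 and 41 at 2 h and 201 lower at 24 h against 2 h, and protein-coding genes only gave 126 higher at 2 h and 205 lower at 24 h against 2 h. Leaving out each library in turn gave 1415 to 1771 higher and 2073 to 2758 lower at 2 h, 2590 to 2971 and 2005 to 2489 at 24 h, and 3218 to 3571 and 2148 to 2443 at 24 h against 2 h. Lists called ranged from 8 to 11, 13 to 15 and 11 to 14 with a library left out. With an estimated correlation camera called 0, 0 and 0 lists, where the lowest adjusted p was 0.213, 0.175 and 0.0855, and fry called 16 and 23 in the comparisons with naive.

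The filter at 5 RPKM gave 687 early and transient rises, 886 early and transient falls and 593 genes lower at both times. The class of genes higher at both times that also changed back held 81 genes, and 51 with no filter, 151 with library weights, 47 without both libraries numbered 4 and 50 to 118 with a library left out. The class lower at both times that also changed back held 121, and 238 with library weights, 72 without both libraries numbered 4 and 75 to 210 with a library left out. Genes higher at 2 h and lower at 24 h were 126 to 207 with a library left out. The cause was not tested, except that the filter tests fewer genes and a left-out library leaves fewer samples.

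With the replicate number as a block, 4020, 5107 and 5877 genes were called in the 3 comparisons, and without both libraries numbered 4 these were 3590, 4526 and 5635. Libraries with the same number correlated at -0.043 to 0.055 in their deviations from the group means over 12 pairs, 0 of them over 0.1, and in 3 the best match was the own number, so the numbers do not pair the libraries. Of the values of named genes under other settings, 7119 kept their side of the threshold, 77 lost the call and 96 gained it, and for lists these were 2194, 81 and 56. Among those kept, 38 gene and 68 list values called in neither fit turned their sign. No called direction turned, but Chil3 at 24 h against naive, not called as reported, was called lower with quantile normalisation (-0.46). The difference of Chil3 between 24 h and 2 h (log2 fold change 0.66) was 0 with quantile normalisation, which is counted as a lost call, a choice made after seeing it. Library totals of 6112586 to 11997945 reads limit what can be seen in short genes.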
